A study of Mus musculus with 18 samples.

How the data were processed

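Messenger RNA of mouse embryos (Mus musculus, strain C57BL/6 per the labels) was profiled at embryonic days 9.5, 11.5 and 12.5 in wild-type embryos and in embryos carrying a knockout of Pitx1, a homeodomain transcription factor of the hindlimb. Tissue was the hindlimb field with the adjoining trunk at E9.5 and the hindlimb at the later stages. Each of the 6 groups held 3 libraries, 18 in all. Per the labels' protocols, total RNA was isolated with a mirVana kit, libraries were made with a stranded TruSeq mRNA kit and sequencing was done on a NextSeq instrument. Nothing in the labels says whether the replicates of a group came from separate embryos or litters, so p-values measure only the spread between these libraries, which may in part be technical.

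Per the submitters' processing notes, FastQC, TopHat2 and Cuffdiff were used on mouse build mm9, with no versions given. The annotation and the strand setting are not given in the sources used here. Each stage had its own Cuffdiff table with a line per gene and library. Per the file headers, the deposited values comprise raw fragments, which are estimated counts that need not be whole. Scaled fragments, a signal equal to the raw fragments times 1 factor per library, were deposited beside them per the file headers and entered no test. The RPKM values, in the authors' normalization per kilobase and library size, were deposited in the same tables and give the expression levels in the text. Cuffdiff numbers the replicates of a group from 0 in the tables, and these were taken in order as replicates 1 to 3. Only the replicate numbers rest on that step, since genotype and stage are named in the tables. The tables were normalized separately, so RPKM levels were tested only within a stage.

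The tables listed 23929 genes each. Of these, 25 names had been turned into dates by spreadsheet software, and the 2 date names that each stand for 2 genes were left out. A further 6 genes, among them Eef1a1, were left out because Cuffdiff had failed to estimate them in at least 1 library. Fragment values were rounded to whole numbers before the tests, and 1.79% of them were not whole. Genes with near-identical copies are uncertain, because the way in which fragments shared between copies were assigned is not given. Depth ranged from 14433301 to 60672151 fragments per library. No pair of replicates agreed within sampling noise, with a chi-square per degree of freedom of at least 8.26, so every library counted as 1 replicate.

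Genotypes were compared within each stage with edgeR 4.0.16 in R 4.3.3. The fit used TMM scaling, filterByExpr, robust dispersions and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the F statistic, and fold changes are knockout minus wild type throughout. Differences of the knockout effect between stages were tested as interaction contrasts in group-means fits of 12 libraries. Gene lists were tested with camera in limma 3.58.1 on log2 CPM values with a prior count of 2 and a preset correlation of 0.01, adjusted over 28 lists at 3 stages, 84 tests in all. An estimated correlation and fry served as alternatives. The lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The 502 listed genes found in the tables covered limb patterning, cartilage, bone, joint, muscle, connective tissue, proliferation, stress and markers of other cell types.

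Named genes were a fixed set of 18 limb genes and, per stage, the 10 with the largest rise and the 10 with the largest fall. The latter had to pass the threshold, reach a mean of 1 RPKM in a genotype and show no overlap between genotypes. Up to 4 members of each list past the threshold, and up to 5 genes per direction past the threshold in each difference between stages, were added. Not every gene the rule takes in is printed. Genes named outside this rule are said to be chosen after their values were seen.

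Alternatives were RLE size factors, DESeq2 1.42.0, limma on log2(RPKM + 1) or log2(RPKM + 0.1), no filter, a mean of 5 RPKM, no robust step, all 18 libraries in 1 fit, the replicate number as a block, an added 1.5-fold threshold and leaving out each library. Those chosen after the data were seen are named in the closing section. Each test was checked on simulated counts with the real means, library sizes and dispersions and 200 genes of known change. For E9.5, 13611 simulated genes were tested and 70% of the 50 genes changed by 2-fold were recovered, with 19 false calls over all fold sizes. The same step recovered 84% of such genes among 14481 for E11.5, with 17 false calls, and 80% among 14372 for E12.5, with 11 false calls. For genes changed by 1.5-fold the recovered shares were 48%, 52% and 54%. For the difference between E12.5 and E11.5, 68% of 50 genes with a 2-fold difference were recovered among 15166, and for that between E11.5 and E9.5 50% among 15165. Benjamini-Hochberg adjustment is easier to pass the more genes change, and each simulation held 200 changed genes. The real E9.5 and E12.5 fits called only 3 and 2 genes, so the simulated shares do not carry over to them. Simulated genes also varied independently of each other, which real ones need not do. All these shares may therefore overstate recovery in real data. In the real E12.5 fit Pitx1, at a log2 fold change of -2.92, did not pass (adjusted p = 0.125, edgeR). Gene order came from RefSeq on assembly GRCm38, which is not the build of the tables, so no coordinates are given. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.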

Results

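Expression was measured by RNA sequencing in 18 libraries of the developing mouse hindlimb. They form 6 groups of 3, wild type and Pitx1 knockout at E9.5, E11.5 and E12.5. Depth moved with genotype at the earlier stages. At E9.5 the libraries held 20673065 to 40020110 fragments in the wild type and 14433301 to 18648021 in the knockout. At E11.5 they held 38770845 to 40973174 in the wild type and 44986881 to 60672151 in the knockout. At E12.5 the ranges overlapped, with 24290472 to 39397236 and 22487030 to 30166719 fragments. The design asks how loss of PITX1, the transcription factor that distinguishes the hindlimb from the forelimb, alters gene expression as the limb bud forms cartilage and muscle.

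Pitx1 RNA was lower in every knockout library than in every wild-type library of its stage. At E9.5 it measured 54.8 ± 5.55 RPKM in the wild type and 22.5 ± 3.63 in the knockout (SD, n = 3 each), a log2 fold change of -1.28 ± 0.13 (SE, adjusted p = 0.0231, edgeR). At E11.5 the levels were 119.7 ± 16.3 and 20.2 ± 2.96 RPKM, a log2 fold change of -2.57 ± 0.13 (adjusted p = 6.52e-05, edgeR). At E12.5 they were 90.4 ± 39.7 and 11.9 ± 1.32 RPKM, a log2 fold change of -2.92 ± 0.40 that did not pass the threshold (adjusted p = 0.125, edgeR). The wide wild-type spread at E12.5 came from replicate 3, with 44.6 RPKM against 114.2 and 112.5 in the other two. Without that library the log2 fold change of Pitx1 at E12.5 was -3.24 (adjusted p = 3.14e-06, edgeR). Knockout RNA remained at 41.1%, 16.9% and 13.2% of the wild-type level at the successive stages, and the labels do not say which part of the gene the allele lacks.

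**Figure D1:**
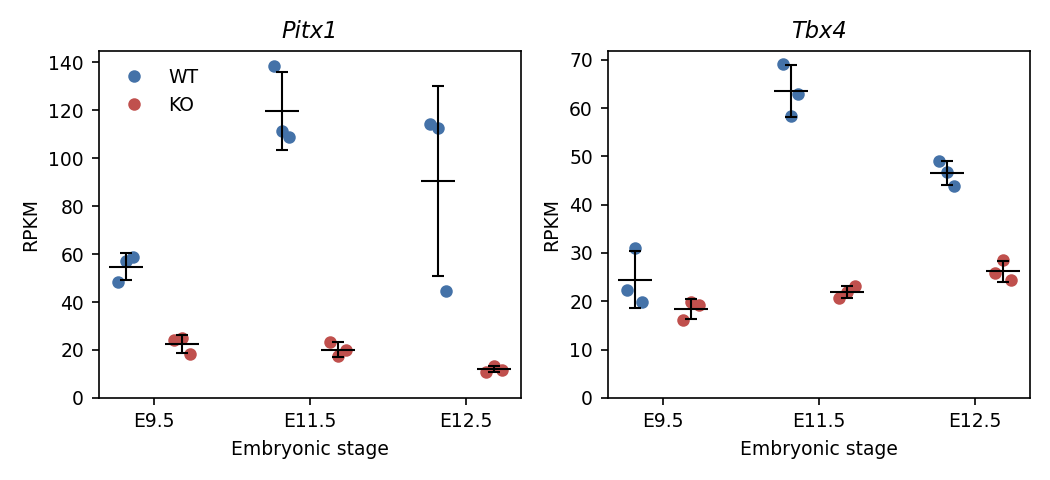
Levels of Pitx1 and Tbx4 in RPKM (y axis) at each embryonic stage (x axis), with wild-type libraries in blue and Pitx1 knockout libraries in red. Points are single libraries, and black lines give the mean and SD of 3; Tbx4 at E11.5 measured 63.6 RPKM in the wild type and 21.99 in the knockout.

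At E9.5, in the hindlimb field with its trunk, Pitx1 was joined by only 2 other genes past the threshold, and all 3 were lower in the knockout. Zfp429, a zinc finger gene, measured 1.77 ± 0.269 RPKM in the wild type and 0.0179 ± 0.0310 in the knockout, with 284 fragments against 2 over the 3 libraries of each genotype (log2 fold change -6.29 ± 0.71 SE, adjusted p = 0.0362, edgeR). Per total fragments that is a ratio of 83.6, with an exact 95% interval from 22.9 to 694 that covers counting error only. Gpr137b-ps, a pseudogene of Gpr137b, measured 3.66 ± 0.815 and 0.573 ± 0.0750 RPKM (log2 fold change -2.67 ± 0.26 SE, adjusted p = 0.0231, edgeR). Tbx4, a T-box gene of hindlimb outgrowth, lay at 24.4 ± 5.88 and 18.4 ± 1.99 RPKM (adjusted p = 0.999, edgeR), and Fgf10, the growth factor that starts limb outgrowth, at 3.33 ± 0.922 and 2.04 ± 0.517. Isl1, which acts upstream in the hindlimb field, lay at 15.0 ± 0.305 and 22.6 ± 1.23 RPKM with no overlap between genotypes and did not pass (log2 fold change 0.59 ± 0.091 SE, adjusted p = 0.277, edgeR).

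The myogenic genes Myod1 and Myog and the cartilage genes Acan and Gdf5 were too low for a test at E9.5. Pax3, a marker of muscle precursors and dorsal neural tissue, lay at 13.7 ± 1.91 and 15.3 ± 0.741 RPKM, and Sox9, the main cartilage regulator, at 6.71 ± 3.49 and 8.26 ± 3.997. Hoxc10 measured 70.8 ± 9.5 and 77.8 ± 10.4 RPKM and Shh 9.60 ± 1.62 and 9.999 ± 1.52, each within the spread of the libraries. Col2a1, Fgf8, Hoxc11, Myf5 and Tbx5 did not pass either, with log2 fold changes from -0.51 for Tbx5 to 0.51 for Hoxc11.

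Among the fixed lists, 6 passed camera's test at E9.5, none with an estimated correlation (adjusted p from 0.570 to 0.667). With adjustment within the stage only 1 list passed, and 9 of the 10 splits of the libraries, the real one included, gave as many. All 15 measured red blood cell genes had positive fold changes, with a median log2 of 0.38 and adjusted p = 1.35e-08, and none passed singly. Hedgehog and posterior limb genes lay higher (19 measured, median 0.12, adjusted p = 0.0264), as did neural crest and Schwann cell genes (10 measured, median 0.31, adjusted p = 0.0320). Muscle differentiation genes lay lower (20 measured, median -0.32, adjusted p = 0.0379), as did osteogenesis genes (9 measured, median -0.37, adjusted p = 0.0429) and endothelial genes (20 measured, median -0.16, adjusted p = 0.0248). Adjusted over the list alone, 2 hedgehog genes passed higher and no gene of the other 5 lists did. The 22 other lists did not pass (adjusted p from 0.0726 to 0.967). Of the 6, only red blood cell genes kept the set call without each library. The call was lost without wild-type replicate 1 for hedgehog and muscle differentiation genes (adjusted p = 0.175 and 0.105), without replicate 2 for muscle differentiation and endothelial genes (0.118 and 0.313) and without replicate 3 for muscle differentiation, neural crest and osteogenesis genes (0.298, 0.208 and 0.36). Without knockout replicate 1 it was lost for all 5 (adjusted p from 0.114 to 0.788), without replicate 2 for hedgehog genes (0.113) and without replicate 3 for muscle differentiation, neural crest and osteogenesis genes (0.407, 0.196 and 0.0689).

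The E9.5 comparison tested 13804 genes, of which 553 had an unadjusted p under 0.05, and DESeq2 called 20. Without knockout replicate 2 there were 2 calls, of which only Pitx1 was shared with the full fit, and without any other library of the stage 0, as in the fit of all 18 libraries.

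**Figure D2:**
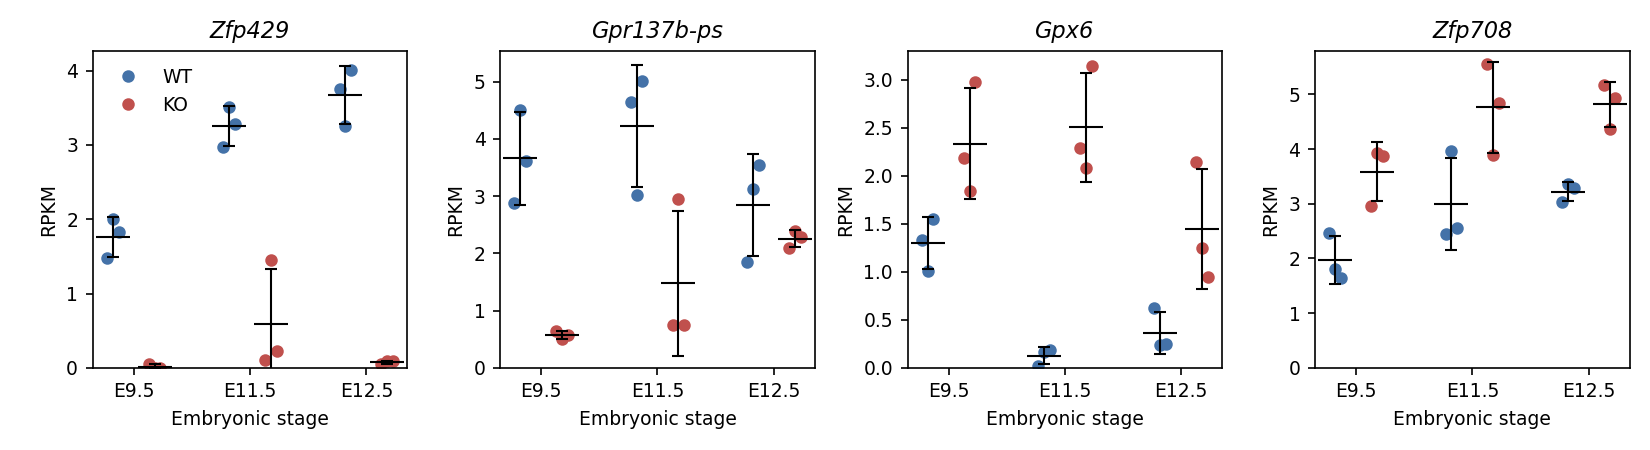
Levels of Zfp429, Gpr137b-ps, Gpx6 and Zfp708 in RPKM (y axes) at each embryonic stage (x axes), with wild-type libraries in blue and Pitx1 knockout libraries in red, the last gene chosen after its values were seen. Points are single libraries and black lines the mean and SD of 3, drawn from 0 up; Zfp429 lay at 1.45 RPKM in knockout replicate 2 of E11.5 and at 0.110 and 0.222 in the other two.

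At E11.5 the knockout hindlimb had less RNA for the hindlimb gene Tbx4, for the cartilage genes Sox9 and Col2a1, and for the muscle genes Pax7, a precursor marker, and Tnni1, a contractile gene. The mitotic genes Ccnb1, Ccnb2, Kif11 and Top2a, the pro-apoptotic gene Pmaip1 and the late Hox genes Hoxa11 and Hoxd11 rose. In all, 286 of 14601 genes passed, 138 higher and 148 lower in the knockout, and of the 130 that changed at least 1.5-fold 28 were higher and 102 lower. Falls outnumbered rises among the larger changes.

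Of 19 measured genes of hindlimb identity and initiation, 2 fell and none rose. Tbx4 fell from 63.6 ± 5.42 to 21.99 ± 1.21 RPKM (log2 fold change -1.53 ± 0.085 SE, adjusted p = 6.32e-05, edgeR), and Pitx1 was the other. Isl1, Hoxc10, Hoxc11 and Fgf10 did not pass, with log2 fold changes of -0.17, 0.10, 0.10 and 0.46. The list as a set did not pass (adjusted p = 0.796), and 2 members passed higher and 2 lower when adjusted over the list alone. Tbx5, the forelimb counterpart of Tbx4, lay at 0.896 ± 0.419 and 0.278 ± 0.158 RPKM and did not pass (adjusted p = 0.109, edgeR), and none of 9 measured forelimb identity genes did.

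Of 34 measured chondrogenesis genes, 6 fell, none rose and 28 did not pass, and 31 had negative fold changes with a median log2 of -0.96. Sox9 fell from 47.6 ± 4.12 to 27.6 ± 4.31 RPKM (log2 fold change -0.79 ± 0.12 SE, adjusted p = 0.0198, edgeR). Col2a1, the main cartilage collagen, fell from 113 ± 18.2 to 52.1 ± 10.99 RPKM (-1.12 ± 0.17 SE, adjusted p = 0.0317, edgeR). Lect1, which encodes chondromodulin, fell from 8.70 ± 3.44 to 1.03 ± 0.671 RPKM. Matn1, a cartilage matrix gene, fell by 5.56 on the log2 scale and Cytl1 fell by 1.96. The sixth, Wwp2, lies outside the rule for named genes and was chosen after its values were seen; it fell by 1.07. Acan, the aggrecan gene, lay at 0.783 ± 0.921 and 0.0439 ± 0.0555 RPKM (adjusted p = 0.220, edgeR), and Gdf5, a joint gene, at 10.7 ± 3.88 and 4.21 ± 2.03 (adjusted p = 0.146, edgeR). For Gdf5 at E11.5 adjusted p was 0.0324 without knockout replicate 1 and from 0.106 to 0.395 without each other library. The count adjusted over the list alone was 9. The set test gave adjusted p = 6.60e-11, and adjusted p = 0.570 with an estimated correlation.

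Myogenic progenitor and regulator genes lay lower in all 21 cases, with a median log2 of -0.81, and 6 fell. Msc, which encodes musculin, fell from 8.65 ± 1.17 to 3.29 ± 0.490 RPKM, Cdh15, the muscle cadherin, from 4.85 ± 1.59 to 2.08 ± 0.168 and Pax7 from 0.415 ± 0.0798 to 0.0517 ± 0.0334. Mef2c fell by 0.87 on the log2 scale and counts also under osteogenesis. The master regulators Myod1 and Myog lay at 12.7 ± 3.89 against 4.24 ± 1.43 and at 20.4 ± 8.90 against 4.41 ± 2.23 RPKM without passing (adjusted p = 0.0608 and 0.106, edgeR). Myf5 and Pax3 had log2 fold changes of -0.81 ± 0.27 and -0.33 ± 0.32 (SE). When adjusted over the list alone 17 passed, and the set test gave adjusted p = 2.20e-12, or adjusted p = 0.394 with an estimated correlation.

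The muscle differentiation list showed the largest median of the 28 lists at this stage, a log2 of -2.44. Of 39 measured members 38 had negative fold changes, and 8 fell. Acta2, a smooth muscle actin also used in early muscle, fell from 17.0 ± 2.55 to 2.80 ± 1.08 RPKM (log2 fold change -2.59 ± 0.29 SE, adjusted p = 0.0208, edgeR). Myl1, Smyd1 and Tnni1, genes of the contractile apparatus and its assembly, and Atp2a1, a calcium pump gene, had log2 fold changes of -3.22, -3.04, -2.44 and -2.28 and fell. The count adjusted over the list alone was 31, and the set test gave adjusted p = 5.06e-18, or adjusted p = 0.570 with an estimated correlation.

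Tendon and muscle connective tissue genes lay lower (20 measured, median log2 -0.52, set adjusted p = 5.65e-05, adjusted p = 0.570 with an estimated correlation), and 2 fell. These were Col3a1, from 191 ± 13.8 to 139.8 ± 8.88 RPKM, and Tcf7l2, a marker of muscle connective tissue, from 16.01 ± 2.12 to 10.5 ± 1.43. Of 13 somite and sclerotome genes, Foxc1 and Tbx18 fell, with log2 fold changes of -0.59 and -0.64 (set adjusted p = 0.0149, adjusted p = 0.570 with an estimated correlation). Osteogenesis genes had a median log2 of -0.39 over 11 measured members (set adjusted p = 0.0223, adjusted p = 0.581 with an estimated correlation), with Mef2c the one that fell. When adjusted over the list alone, 6 connective tissue, 2 somite and 2 osteogenesis genes passed lower. The set call was lost for somite genes without wild-type replicate 3 (adjusted p = 0.0509) and for osteogenesis genes without wild-type replicate 2 (adjusted p = 0.0508).

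All 30 proliferation genes had positive fold changes, with a median log2 of 0.20, and 4 rose. Ccnb1 and Ccnb2, cyclins of mitosis, rose from 44.7 ± 3.46 to 62.0 ± 4.31 RPKM and from 99.95 ± 4.67 to 127 ± 6.41, and the mitotic genes Kif11 and Top2a by log2 fold changes of 0.43 ± 0.076 and 0.37 ± 0.076 (SE). With p adjusted over the list alone 13 passed, and the set test gave adjusted p = 1.48e-09, or adjusted p = 0.570 with an estimated correlation. Pmaip1, a p53 target that promotes cell death, rose from 57.5 ± 3.35 to 118 ± 7.96 RPKM (log2 fold change 1.04 ± 0.079 SE, adjusted p = 0.000327, edgeR), while the other 16 measured genes of the p53 list did not pass and the set did not either (adjusted p = 0.304). Hoxd11 and Hoxa11, which pattern the middle of the limb, rose from 23.4 ± 1.02 to 34.7 ± 3.93 and from 39.7 ± 3.17 to 56.2 ± 3.73 RPKM. Hand1 fell from 0.884 ± 0.448 to 0.134 ± 0.0740 RPKM. Shh and Fgf8, the signals of the posterior limb and the ridge, lay at 2.02 ± 1.70 against 2.83 ± 1.76 and at 10.8 ± 2.91 against 14.6 ± 2.27 RPKM and did not pass.

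The rule for the largest changes took in further genes. Rises were Gpx6, a glutathione peroxidase gene, from 0.124 ± 0.0882 to 2.50 ± 0.565 RPKM (log2 fold change 4.31 ± 0.52 SE, adjusted p = 0.00775, edgeR), the histocompatibility gene H2-Q7, and Hax1, Pgam1, Mrps10 and Rasl2-9, with log2 fold changes from 0.85 for Mrps10 to 1.22 for H2-Q7. The falls included Afp, the yolk sac and liver protein alpha-fetoprotein, from 4.23 ± 0.781 to 0.260 ± 0.116 RPKM, Mip from 1.16 ± 0.141 to 0.135 ± 0.0960 and E130114P18Rik from 6.76 ± 1.51 to 0.820 ± 0.288. Apob and Alb, further liver and yolk sac genes, were chosen after their values were seen. Apob fell with Afp, from 29, 33 and 47 fragments in the wild-type libraries to 0, 4 and 2 in the knockout, while Alb, with 3 to 19 fragments per library, overlapped between genotypes. At E12.5 wild-type replicate 1 held the highest levels of all 3 genes, with Afp at 273 RPKM, Apob at 2.19 and Alb at 4.96, and none of the 3 passed there. Brachyury (T), a notochord gene, fell by 2.22 on the log2 scale. Ndufs5, Eno1 and Rps15a-ps6 have near-identical copies and are uncertain. The microRNA genes Mir703 and Mir546 are very short, so RPKM overstates their levels, and their rises of 1.11 and 1.36 in log2 are uncertain too.

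Markers of other cell types moved as well. Macrophage genes lay lower (18 measured, median log2 -0.57, set adjusted p = 0.000586, adjusted p = 0.570 with an estimated correlation) and surface ectoderm genes higher (20 measured, median 0.32, set adjusted p = 0.000109, adjusted p = 0.570 with an estimated correlation), with no member past the threshold over all genes. With p adjusted over the list alone, 5 macrophage genes passed lower, and 9 surface ectoderm genes passed higher and 1 lower. Endothelial genes had a median log2 of -0.19 (20 measured, set adjusted p = 0.0363, adjusted p = 0.667 with an estimated correlation), with no member past the threshold over the list alone. Of 17 hypoxia and glycolysis genes only Eno1, which is uncertain, fell (median log2 -0.22, set adjusted p = 0.0165, adjusted p = 0.570 with an estimated correlation). Without wild-type replicate 3 the set call was lost for hypoxia and glycolysis genes (adjusted p = 0.0509) and endothelial genes (0.328), and without knockout replicates 1 and 3 for endothelial genes (0.0726 and 0.104). The 17 other lists did not pass at E11.5 (adjusted p from 0.0530 to 0.948), among them anterior limb, apical ridge, joint, immediate early, neural, neural crest, red blood cell, gut, notochord, kidney, germ cell and sex-linked genes and the neighbours of Pitx1.

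The count at E11.5 rested on single libraries. It was 9, 75 and 643 without wild-type replicates 1, 2 and 3 and 599, 135 and 14 without knockout replicates 1, 2 and 3, and DESeq2 called 1280. In all 6 of these fits 7 genes kept their call, among them Afp, E130114P18Rik, Pitx1, Pmaip1, Tbx4 and Itm2a, the last chosen after its values were seen.

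**Figure D3:**
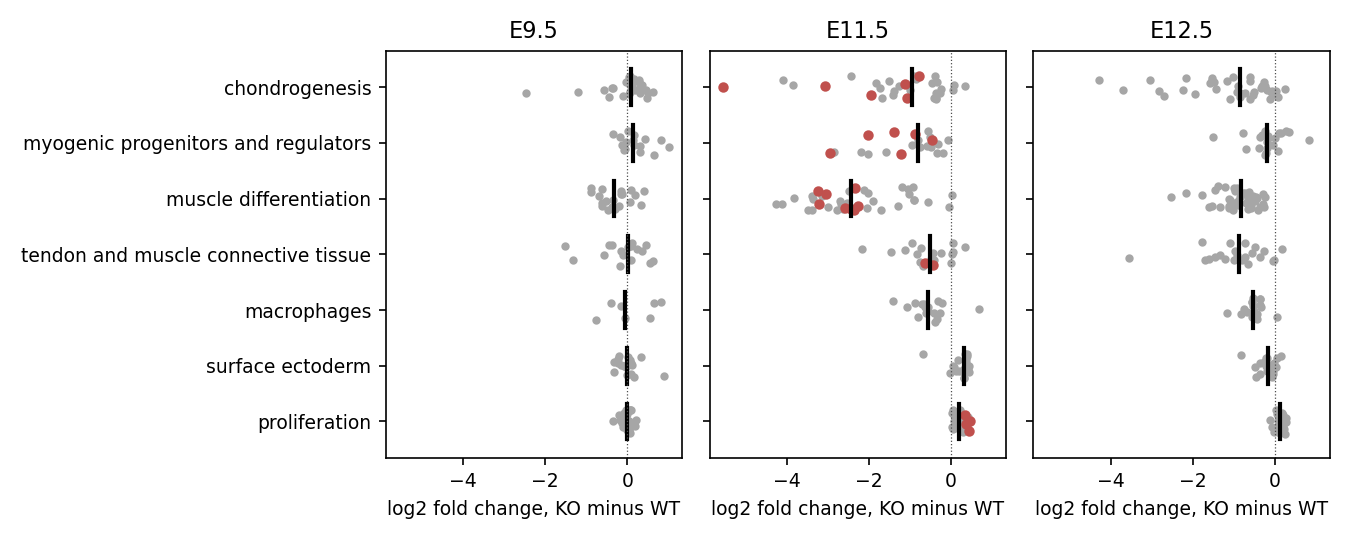
Log2 fold changes, knockout minus wild type (x axis), of the measured members of 7 gene lists (y axis) at each stage. Each point is a gene, red where it passed the threshold over all genes, and black bars are medians; the median of the muscle differentiation list was -2.44 at E11.5 and -0.82 at E12.5.

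At E12.5, only Tbx4 and Zfp429 passed the threshold, both lower in the knockout. With the replicate number as a block, a pairing that the labels do not state, 386 genes passed, 69 higher and 317 lower. Tbx4 fell from 46.6 ± 2.56 to 26.2 ± 2.16 RPKM (log2 fold change -0.83 ± 0.076 SE, adjusted p = 0.0263, edgeR) and Zfp429 from 3.67 ± 0.386 to 0.0741 ± 0.0246 (-5.57 ± 0.30 SE, adjusted p = 0.000789, edgeR). The muscle regulators Myod1, Myog and Myf5 lay at 24.1 ± 3.12 against 20.4 ± 4.93, 69.4 ± 9.84 against 61.1 ± 19.8 and 2.966 ± 0.396 against 2.99 ± 0.391 RPKM, each within the spread of the libraries.

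Of 38 measured chondrogenesis genes, 34 had negative fold changes with a median log2 of -0.86, and none passed over all genes. Adjusted over the list alone, 23 passed lower, and the set test gave adjusted p = 2.66e-15, or adjusted p = 0.570 with an estimated correlation. Col2a1 lay at 189 ± 16.1 and 124 ± 21.6 RPKM (adjusted p = 0.160, edgeR) and Acan at 6.41 ± 2.07 and 1.35 ± 0.809 (adjusted p = 0.215, edgeR), without overlap between genotypes. Sox9 lay at 50.2 ± 14.7 and 47.3 ± 7.58 RPKM. Gdf5 lay at 49.1 ± 3.84 and 26.5 ± 2.84 RPKM, just short of the threshold (log2 fold change -0.89 ± 0.094 SE, adjusted p = 0.0539, edgeR), and for Gdf5 at E12.5 adjusted p was 0.0366 without wild-type replicate 3. Joint interzone genes, a list that includes Gdf5, had a median log2 of -0.28 (16 measured, 4 past the threshold adjusted over the list alone, set adjusted p = 0.00310, adjusted p = 0.570 with an estimated correlation).

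All 46 measured muscle differentiation genes had negative fold changes, with a median log2 of -0.82, and 6 passed when adjusted over the list alone (set adjusted p = 4.82e-18, adjusted p = 0.570 with an estimated correlation). Tendon and muscle connective tissue genes had a median of -0.87 (22 measured, 2 past the threshold over the list alone, set adjusted p = 9.95e-07, adjusted p = 0.570 with an estimated correlation), macrophage genes one of -0.53 (18 measured, 5 over the list alone, set adjusted p = 7.45e-07, adjusted p = 0.570 with an estimated correlation) and osteogenesis genes one of -0.62 (12 measured, 2 over the list alone, set adjusted p = 0.0195, adjusted p = 0.570 with an estimated correlation). Wild-type replicate 3 deviated from the other wild-type libraries by a median log2 of 1.03 in the connective tissue list, 0.35 in muscle differentiation, 0.29 in joint, 0.21 in macrophage and 0.14 in osteogenesis genes, the direction that lowers these fold changes. Without it the set call of osteogenesis genes was lost (adjusted p = 0.0597), as without wild-type replicate 2 (0.0987). Neural genes lay lower too (10 measured, 2 over the list alone, median -0.29, set adjusted p = 0.00749, adjusted p = 0.570 with an estimated correlation), as did neural crest and Schwann cell genes (13 measured, median -0.31, set adjusted p = 0.0424, adjusted p = 0.667 with an estimated correlation). The latter call was lost without wild-type replicates 2 and 3 (adjusted p = 0.105 and 0.253) and without knockout replicates 1 and 2 (0.138 and 0.269). Proliferation genes lay higher (30 measured, median 0.14, set adjusted p = 2.04e-05, adjusted p = 0.667 with an estimated correlation). The 19 other lists did not pass (adjusted p from 0.0848 to 0.796), among them the 22 measured myogenic progenitor and regulator genes with a median of -0.19 (adjusted p = 0.221).

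Of the fixed limb genes, Hoxc10 lay at 18.8 ± 4.50 and 33.9 ± 9.95 RPKM and Pax3 at 0.431 ± 0.158 and 0.759 ± 0.147, and neither passed. Isl1, Hoxc11, Fgf8, Fgf10 and Tbx5 had log2 fold changes of 0.090, 0.0030, 0.69, -0.27 and -0.18 without passing, and Shh was too low for a test. Of 14494 genes tested, 2185 had an unadjusted p under 0.05, and DESeq2 called 452. The count was 15 without wild-type replicate 3, 6 without knockout replicate 1 and 1 without wild-type or knockout replicate 2, while Zfp429 passed in all 6 of these fits. The call of Tbx4 at E12.5 held only without wild-type replicate 3 (adjusted p = 0.00652) and was lost without each other library (adjusted p from 0.0508 to 0.141).

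The knockout effect was then compared between stages, which is the test of whether the changes seen at E11.5 were specific to that stage. Pgm5, which encodes a phosphoglucomutase-like protein of cell junctions, was the one gene with a different effect at E12.5 and E11.5 among 15324 tested. It lay at 5.10 and 2.05 RPKM in wild type and knockout at E11.5 and at 10.2 and 11.1 at E12.5, a difference of log2 fold changes of 1.42 ± 0.18 (SE, adjusted p = 0.0357, edgeR). Tbx4, with log2 fold changes of -1.53 and -0.83, did not pass (difference 0.69 ± 0.11 SE, adjusted p = 0.108, edgeR), so a smaller effect at E12.5 was not shown. Unadjusted p was under 0.05 for 1585 genes, limma on log2(RPKM + 1) called 0, and leaving out libraries moved the count. It was 0 without E11.5 wild-type replicate 1 or 2 or E12.5 knockout replicate 2 or 3, 2 without E11.5 wild-type replicate 3, 5 without E11.5 knockout replicate 1 and 4 without E12.5 knockout replicate 1. For Pgm5 in E12.5 minus E11.5 the call was also lost without E11.5 knockout replicate 3 (adjusted p = 0.0993) and without E12.5 wild-type replicates 1, 2 and 3 (adjusted p = 0.0775, 0.0508 and 0.0769).

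Between E11.5 and E9.5, 4 of 15372 genes differed. Sdc2, a cell surface proteoglycan gene, and the uncertain Mir703 moved upward at E11.5 relative to E9.5, with differences of 1.01 ± 0.13 and 1.57 ± 0.23 (SE), and Rprm and the uncertain Eno1 moved downward by -1.43 ± 0.21 and -7.85 ± 1.02 (adjusted p = 0.0322 for each, edgeR). Pitx1 itself had a difference of -1.29 ± 0.20 (SE, adjusted p = 0.0558, edgeR) and Tbx4 one of -1.12 ± 0.20 (SE, adjusted p = 0.102, edgeR). Stage and tissue differ together in this contrast, since the E9.5 samples held trunk, and unadjusted p was under 0.05 for 2344 genes. The count was 0 without E9.5 knockout replicate 1, E11.5 wild-type replicate 1 or E11.5 knockout replicate 3, 1 without E9.5 wild-type replicate 1, 2 without E11.5 knockout replicate 2, 8 without E11.5 knockout replicate 1 and 9 without E11.5 wild-type replicate 2.

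No gene passed at all 3 stages. Pitx1 passed at E9.5 and E11.5, where independent lists would share 0.0301 genes, Zfp429 at E9.5 and E12.5 (0.000449 by chance) and Tbx4 at E11.5 and E12.5 (0.0206 by chance), all 3 lower in the knockout. That count of 3 was 1 without any E9.5 library other than knockout replicate 2, 6 without E11.5 knockout replicate 2 and 8 without E12.5 wild-type replicate 3. Of the 148 genes that fell at E11.5, 146 were measured at E12.5 and 90.4% of these had a negative fold change there, with medians of -0.80 at E11.5 and -0.28 at E12.5. Of the 138 that rose, 90.6% had a positive fold change at E12.5, with medians of 0.45 and 0.15. At E9.5 the shares with the same sign were 50.4% of 135 and 34.1% of 138. Medians at E11.5 are those of genes picked for their change there and are inflated by that choice. Across 12034 genes, which are not independent replicates, the fold changes of E11.5 and E12.5 had a Pearson correlation of 0.39 and a Spearman correlation of 0.38, against -0.045 and -0.17 for E9.5 and E11.5.

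**Figure D4:**
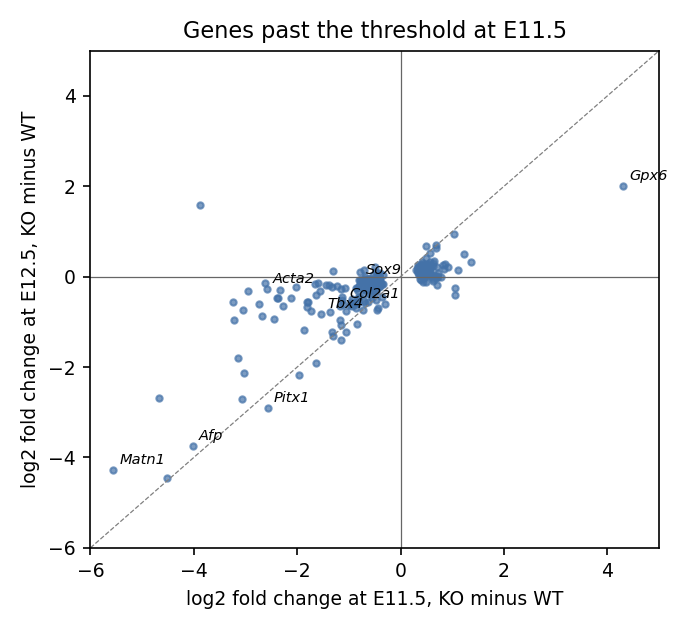
Log2 fold changes, knockout minus wild type, at E11.5 (x axis) and E12.5 (y axis) for 284 genes past the threshold at E11.5 and measured at both stages. Each point is a gene and the dashed line marks equality; 3 genes lie outside the frame, and of the genes lower at E11.5 90.4% lie below 0 at E12.5.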

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

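The tests on Zfp429 alone and on each chromosome were chosen after the values were seen. The test on the genes around Pitx1 was set before its own outcome was known. It was prompted by the changes of Zfp429, Gpr137b-ps and Gpx6 in these same data. A test of the difference between stages picked out 5 genes. Pgm5 had a log2 difference of 1.42 between E12.5 and E11.5, with effects of -1.31 and 0.12 at E11.5 and E12.5. Sdc2 differed by 1.01 between E11.5 and E9.5, Mir703 by 1.57, Rprm by -1.43 and Eno1 by -7.85; Eno1 had 0 fragments in the E11.5 knockout libraries, so this fitted value is no bound. Splits of the libraries within stages gave at least as many genes as the real 1 for E12.5 and E11.5 in 10 of 100 drawn splits, the real one included, with up to 863 in another, and at least as many as the real 4 for E11.5 and E9.5 in 9 of 100, the real one again included, with up to 690 in another. Most of the other splits that reached the real counts, with the highest among them, kept the genotypes of E11.5 whole and mixed those of the other stage. The genotype effect at E11.5 enters their counts, so these shares of splits do not measure chance. A split that mixed both stages gave 47 genes for E11.5 and E9.5. Chance is not excluded for either count.

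Zfp429, Gpr137b-ps and Gpx6 share the chromosome of Pitx1 in the gene order of GRCm38, and each passed the threshold in the knockout at some stage. Strain variants linked to the targeted allele would alter other genes there too. Of the other genes of that chromosome tested, 4.47% changed by at least 2-fold with unadjusted p under 0.01 at some stage. Elsewhere 2.20% did (odds ratio 2.08, two-sided Fisher's exact p = 0.00218), which goes with linkage but does not single it out. At E9.5, E11.5 and E12.5 the odds ratios were 7.55, 2.10 and 1.91 (two-sided Fisher's exact p = 0.0011, 0.0198 and 0.0541). The changed genes included Gpr137b at E9.5 and Hapln1, of the chondrogenesis list, at E12.5, both picked after their values were seen. The test thus does not set linked changes apart from the knockout response. The window of 500 genes on each side reached both ends of the chromosome, whose odds ratio ranked 1 of 20 chromosomes (adjusted p = 0.0436). Direct loss of PITX1 acting on Zfp429 stays open, because the highest knockout library, E11.5 replicate 2, held 44.5% of the wild-type mean with Pitx1 at 17.3 RPKM while the other E11.5 knockout libraries held 3.38% and 6.80%, and 1 library cannot exclude it. Gpr137b-ps lay at 2.94 RPKM in that library against 0.740 and 0.754, and at 2.26 ± 0.148 in the knockout against 2.84 ± 0.889 at E12.5, so linked segments that differ between embryos are a candidate explanation, untested, as are reads shared with Gpr137b, a gene chosen after its values were seen, whose log2 fold changes were 1.04, 0.95 and 0.49 without passing.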

How the results depend on the processing

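The alternatives for genes shared between stages, other than log2(RPKM + 1) and 1.5-fold, and the leaving out of libraries for the differences between stages were chosen after the data were seen, as were those for the lists other than log2(RPKM + 1), the block, the estimated correlation and fry. The main counts were 3, 286 and 2 genes at E9.5, E11.5 and E12.5, 3 genes shared between stages, 26 lists, 1 gene for the difference between E12.5 and E11.5 and 4 for that between E11.5 and E9.5. RLE size factors gave 3, 289 and 2, and no robust step 2, 210 and 2. DESeq2 gave 20, 1280 and 452 genes, which include all main calls, and 121 shared. With limma on log2(RPKM + 1) the counts were 6, 220 and 4, 5 shared, and 0 for E12.5 against E11.5; with log2(RPKM + 0.1) they were 5, 214 and 5. No filter gave 4, 525 and 5. A mean of at least 5 RPKM, which tests fewer genes, gave 1, 340 and 1, 16 lists, and 2 for E11.5 against E9.5. All 18 libraries in 1 fit gave 0, 692 and 23 genes, 9 shared, 0 for E12.5 against E11.5 and 15 for E11.5 against E9.5. The added 1.5-fold threshold left 130 genes at E11.5 by its construction. An estimated correlation left 0 lists and directional fry 3, while fry for either direction gave 30. The 3 were lists of E11.5, namely myogenic progenitors and regulators, hypoxia and glycolysis (adjusted p = 0.0192 each, directional fry) and somites and sclerotome (0.0395). Chondrogenesis and muscle differentiation genes at E11.5 did not pass it (adjusted p = 0.159 and 0.175, directional fry). Leaving out 1 library gave 0 to 2, 9 to 643 and 1 to 15 genes at the successive stages, 1 to 8 shared, 20 to 36 lists, 0 to 5 for E12.5 against E11.5 and 0 to 9 for E11.5 against E9.5. Except where stated, the cause was not tested.

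Replicate numbers were not taken to pair the libraries, because at no stage did every pair of wild type and knockout with the same number deviate together from the group means at a correlation over 0.1. For replicates 1, 2 and 3 the correlations were 0.02, -0.39 and -0.37 at E9.5, 0.04, -0.23 and 0.05 at E11.5 and 0.17, -0.03 and 0.23 at E12.5, where a shared source of replicates 1 and of replicates 3 stays open. The number as a block gave 0, 100 and 386 genes, 26 shared, 26 lists and 1 for E11.5 against E9.5. For named genes past the threshold, 512 of 723 combinations of gene and alternative kept direction and call, 211 kept direction only and 0 reversed. Among lists past the threshold, the median, the mean and the test had the same sign. At the E9.5 depth, 48% of simulated 1.5-fold changes were recovered, so many changes of that size would be missed. The real share may be lower still, since the simulated genes varied independently of each other.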

Other observations

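The families by symbol and the tests on muscle precursors and on Tbx4 were chosen only after the results were seen. The tests of delay and of the wild-type library of E12.5 that stood apart were prompted by patterns in these same data. For the remaining values of this part, no choice before the results were seen is claimed. Of the 15 families, 1 passed its test at E11.5. The family called Sm and LSm here was taken by Snrp and Lsm symbols, which also admit other spliceosome genes, Snrpb2 among them. Of its 22 measured genes, 4 rose, namely Lsm6, Snrpb2, Snrpd1 and Snrpf, with log2 fold changes of 0.68 ± 0.092, 0.62 ± 0.10, 0.44 ± 0.095 and 0.71 ± 0.11 (SE). That is more than the share of all tested genes that rose (hypergeometric adjusted p = 0.00147 over 30 tests of 15 families). The adjustment does not cover the choice of families after the results were seen, and the test takes genes as independent. Without E11.5 wild-type replicate 1 only 2 of all genes rose, and without E11.5 knockout replicate 3 only 3. These 4 calls therefore cannot all hold in those fits. Fold changes at E11.5 also went down with transcript length, at a Spearman correlation of -0.11, and 35 of 38 proteasome genes and 22 of 30 complex I genes had positive fold changes without any passing. The median of the Sm and LSm genes at E11.5 was 0.22 under TMM and RLE scaling, and at E12.5 all 21 measured Sm and LSm genes fell short of the threshold with a median of 0.073. Of 9 measured genes of the insulin-like growth factor system, Igf2 and Igfbp3 fell, with log2 fold changes of -0.46 and -0.78 but the family did not pass (adjusted p = 0.0526), and of 39 collagen genes Col2a1, Col3a1 and Col25a1 fell without the family passing (adjusted p = 0.0714, median -0.37). Cytosolic and mitochondrial ribosomal protein genes had medians of 0.14 and 0.15, and Mrps10 was the one member past the threshold.

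A knockout limb earlier on the programme from E11.5 to E12.5 is a candidate explanation for the low cartilage and muscle genes of E11.5. Of the genes past the threshold at E11.5, 76.9% moved against the wild-type change from E11.5 to E12.5, against 61.5% of all tested genes, 68.9% of genes that fell, 85.5% of genes that rose, and 18 of 20 cartilage and muscle genes that fell beside 87.2% of all measured members of those lists. The same wild-type libraries of E11.5 enter both sides, which shifts these shares by an amount not measured, so delay stays open. Delay as the cause of low Tbx4 at E12.5 is argued against, since its highest knockout library reached 83.0 CPM against at least 127.8 in every wild-type library of both stages. An even loss of muscle-lineage cells is argued against by the medians of the regulator and differentiation lists, which differed by 1.63 on the log2 scale (permutation p = 0.00012). Pax3, Lbx1 and Myf5 lay at -0.33, -0.75 and -0.81. The regulators Pax7, Myog and Vgll2 lay nearer the differentiation median of -2.44, at -2.95, -2.20 and -2.03. So did Gm7325 and Tmem8c, at -2.86 and -2.03, which are in the regulator list but are muscle fusion genes. Vgll2, Gm7325 and Tmem8c were picked after their values were seen. Loss of some muscle cells therefore stays open, as does a late start of differentiation, which was not tested.

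Wild-type replicate 3 of E12.5 stood apart, with Pitx1 at 44.6 RPKM against 114.2 and 112.5 in the other two, and log2 deviations from the other wild-type libraries with medians of 1.03 in connective tissue genes and -0.94 in red blood cell genes. Its deviation correlated across 12242 genes at 0.34 with the knockout change from E11.5 to E12.5, which is consistent with tissue further along that programme than wild-type replicate 1, which showed -0.35. These values mirror each other, since deviations within a group balance out, and those of knockout replicates 1 and 3, at -0.34 and 0.38, come from libraries that enter the change itself. Wild-type and knockout replicates 1 lay alike here, as did replicates 3, and a shared source of each stays open. Knockout tissue in it is argued against, since its deviation correlated at -0.08 with the knockout effect at E11.5 and Tbx4 deviated by -0.13 where Pitx1 deviated by -1.35. 

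With 3 libraries against 3 there are 10 splits per stage, too few for a share under 0.05. At E9.5 the real split gave 3 genes and the highest other 54, and 2 splits, the real one included, gave as many. At E11.5 the real split gave 286 genes and the highest other 0, so only the real split reached that count. At E12.5 the real split gave 2 and the highest other 1, again with 1 split, the real one, reaching the count. Lists past the threshold with adjustment within the stage numbered 1, 12 and 9 in the real splits, with highest others of 13, 10 and 11, and 9, 1 and 6 splits gave as many, the real ones included. The E9.5 split with 54 genes, several times the real count, set wild-type replicate 2 with knockout replicates 1 and 3 and points to a structure of the samples other than genotype.

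All 18 libraries had Ddx3y at 8.87 RPKM or more and Xist at 0.156 RPKM or less. Levels of Ndufs5 ran from 0 to 54.2 RPKM over the 18 libraries and those of Ahcy, chosen after its values were seen, from 1.77 to 15.7. These genes with near-identical copies are therefore uncertain. The correlation of fold changes with transcript length across 14601 genes at E11.5 compares with -0.040 at E9.5 and -0.056 at E12.5, and at E11.5 the median length was 2270 bases for genes that rose and 3470 for those that fell.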
